A study of Mus musculus with 6 samples.

How the data were processed

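The data are RNA-seq expression values of 6 libraries from peritoneal macrophages of C57BL/6 mice, 3 given vehicle and 3 given R-2-HG at 0.1 mM for 24 h. Per the labels' protocols, total RNA was extracted with a spin-column kit for small samples, treated with DNase, and made into libraries by standard Illumina protocols. The authors deposited 1 table of 34745 genes with FPKM values in 1 column per library, and these FPKM were used as deposited. Bowtie 0.12.2, Cuffdiff and the genome builds mm8 and mm10 are named in the submitters' processing notes, which give no role or order; strand handling and the annotation are not given in the sources used here. FPKM divides by transcript length and library total, so it keeps no counts, and tests for counts could not be applied; an alternative planned for counts only was therefore not run.

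Each column was matched to a library by its name, no per-sample column was left unmatched, and no pair of libraries held identical values. The table paired gene identifiers with symbols. A spreadsheet had turned 27 symbols into dates, and all 27 were restored from the gene identifier. Of the identifiers, 34267 were found in GENCODE release M21 (GRCm38), which gave locations, biotypes and exon lengths and need not be the annotation the authors used. Where several gene models carried 1 symbol (65 repeats), the one with the highest mean over all 6 libraries stood for it in gene lists.

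Depth was estimated from the steps between low FPKM values. In 7051 genes with a single transcript and over 1000 bp of exon, FPKM times length comes in whole multiples of the value of 1 fragment. Between 93.6% and 95.8% of the low values per library lay within 0.1 of a whole number of fragments, and the estimates were 15800000, 15500000 and 16610000 fragments for vehicle libraries 1, 2 and 3 and 16350000, 13680000 and 14640000 for R-2-HG libraries 1, 2 and 3. At that depth 1 fragment of a 2 kb transcript is worth between 0.0301 and 0.0365 FPKM, and differences of that size are not detectable. FPKM summed to between 271978 and 302589 per library.

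Genes with a mean of at least 1 FPKM over all 6 libraries (9701) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend and robust estimation), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A change is the R-2-HG mean minus the vehicle mean on the log2(FPKM + 1) scale, which understates the change of low genes; its error is the moderated SE, and errors of FPKM are SDs over 3 libraries. An exact permutation test of 3 against 3 cannot go below 0.1, so single genes rest on the limma model. The 29 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 29 lists, of which all held at least 5 tested members. Members were also counted as adjusted over the list alone. Markers of other cell types in the peritoneal cavity were given as values. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

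The genes named in the text follow a rule fixed before the data were examined. It takes, of the genes called without overlap between the groups and with a higher mean of at least 2 FPKM, the 10 with the largest change in each direction, and where fewer than 5 pass in a direction, the 5 with the smallest p in that direction, stated to have missed the threshold. It also takes up to 3 members of each list with the smallest p, of which the text gives at least the first 2 by p, and always 16 genes, of which 1 is not reported here: D2hgdh, Idh1, Idh2, Tet2, Fto, Hif1a, Ldha, Arg1, Mrc1, Nos2, Tnf, Il6, Il1b, Il10 and Adgre1. Cell type markers come from a list fixed at the same time. Ube2l3, C5ar1, Igkc, Grb2 and the genes that differ between replicate numbers were named after their values were seen.

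The titles give each library a replicate number from 1 to 3, shared by the groups, and do not say what it marks. Deviations from the group means of same-numbered libraries correlated across genes at 0.54, 0.38 and 0.36 for numbers 1, 2 and 3, while libraries of different numbers correlated between -0.47 and 0.05. Deviations cancel out within a group, so part of this contrast is built in. Without centring, vehicle libraries 1 and 2 correlated most with their own number (0.9883 and 0.9873). Vehicle library 3 correlated more with R-2-HG library 2 (0.9764) than with R-2-HG library 3 (0.9725). By the criterion that the deviations of all same-numbered pairs correlate above 0.1, the numbers pair the samples, a pairing that comes from the data and not from the labels. The fit with the number as a block was an alternative fixed beforehand. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

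The tests were checked on simulated values with the means and residual spread of the 9701 genes, 200 of them changed. Changes were added on the log2(FPKM + 1) scale, so in genes of a few FPKM they stand for larger changes in FPKM. On that scale, limma without the block recovered 3% of genes changed by 1.5-fold, 58.2% of those changed by 2-fold and 89.4% of those changed by 4-fold, with 0 false calls. Changes well under 2-fold on that scale would mostly be missed, and in low genes so would larger changes in FPKM. With the block limma recovered 71.6%, 97% and 98.5% (48, 65 and 65 genes) with 22 false calls, a larger share of false calls than the threshold of 0.05 allows. Camera recovered 5 of 5 lists shifted by 0.3 (log2) with 0 false calls among 29 simulated lists. That shift exceeds the largest mean change of a real list, -0.126 for the interferon-stimulated genes, so recovery at such sizes was not checked. The simulated lists were random genes with independent noise, so the check does not cover lists whose members vary together. The estimated correlation of real members was 0.33 for interferon-stimulated genes and 0.69 for class II antigen presentation. Other splits of the 6 real libraries into 3 and 3 that part all same-numbered pairs called 4, 2 and 1 lists.

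Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, quantile normalization, centring each library on its median, eBayes without robust estimation, a 2-fold minimum, the replicate block and each library left out in turn, and for lists also an estimated correlation and fry. Added after seeing the data were the block without both libraries of a number, limma's array weights, the block with an estimated correlation, an estimated correlation in the fits with libraries left out, and for lists the other filters and median centring. With an estimated correlation, camera's power depends on the number of libraries, which is small here and smaller with libraries left out. A list could hardly pass in those fits, so its not passing there does not argue against a call.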

Results

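RNA was sequenced from mouse peritoneal macrophages, phagocytes of the abdominal cavity, of the C57BL/6 strain. The cells were kept for 24 h with vehicle or with R-2-hydroxyglutarate (R-2-HG) at 0.1 mM, and each group had 3 libraries, named here by group and replicate number. The unit is FPKM, the fragments of a gene scaled to its transcript length and to the library's mapped fragments, so no total count was given. From the steps between low values the depth was estimated at 15800000, 15500000 and 16610000 fragments in vehicle libraries 1, 2 and 3 and at 16350000, 13680000 and 14640000 in R-2-HG libraries 1, 2 and 3. Between 12817 (R-2-HG library 3) and 15270 (vehicle library 2) genes had a value above 0.

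Macrophage transcripts dominated both groups. Lyz2, which encodes lysozyme, averaged 19619 ± 1402 FPKM in vehicle and 20039 ± 3548 FPKM in R-2-HG (SD, n = 3 each). Cd68 averaged 1184 ± 155 and 1199 ± 191 FPKM, Csf1r, the receptor for macrophage colony-stimulating factor, 223 ± 34.1 and 224 ± 25.4 FPKM, and Adgre1, the F4/80 antigen, 167 ± 27.8 and 152 ± 29.2 FPKM, in the same order. Adgre1 is also on the list of large peritoneal macrophage identity, as are all the other macrophage markers. Of these, Itgam averaged 99.99 ± 4.92 and 81.8 ± 34.6 FPKM in the more abundant of its gene models. The rest were low. Gata6 averaged 2.06 ± 0.950 and 1.59 ± 0.877 FPKM, Icam2 1.38 ± 0.160 and 1.13 ± 0.0944 FPKM and Timd4, below the filter, 0.607 ± 0.389 and 0.639 ± 0.176 FPKM. Markers of T and NK cells stayed low, with Cd3e at 0.321 ± 0.335 FPKM in vehicle and 0.136 ± 0.129 FPKM in R-2-HG. The B cell marker Cd79b averaged 0.685 ± 0.113 FPKM in vehicle and 0.229 ± 0.0790 FPKM in R-2-HG, below the filter for testing. The immunoglobulin heavy chain gene Ighm stood at 32.4, 8.03 and 4.56 FPKM in vehicle libraries 1, 2 and 3 and 5.49, 6.03 and 5.35 FPKM in R-2-HG libraries 1, 2 and 3. Of 6 neutrophil markers, S100a8 averaged 12.4 ± 3.20 and 11.5 ± 4.14 FPKM and Mmp8 26.9 ± 9.89 and 22.1 ± 5.93 FPKM, while S100a9 (0.892 ± 0.290 and 0.955 ± 0.0427 FPKM), Retnlg (0.481 ± 0.218 and 0.766 ± 0.517 FPKM), Ngp (0.323 ± 0.0659 and 0.365 ± 0.0330 FPKM) and Ly6g (0 in 5 of 6 libraries) lay below the filter. The fibroblast collagen gene Col1a1 differed more between libraries of one group than between the groups, at 31.3, 10.9 and 1.46 FPKM in vehicle libraries 1, 2 and 3 and 29.7, 5.36 and 0.965 FPKM in R-2-HG libraries 1, 2 and 3. The markers were not tested as a group.

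The series compares macrophages given R-2-HG with macrophages given vehicle. R-2-HG is the metabolite that mutant isocitrate dehydrogenases 1 and 2 produce, and it competes with 2-oxoglutarate in enzymes that use the latter. None of the genes of 2-hydroxyglutarate metabolism or of its known targets named here passed the test. Idh1, the cytosolic isocitrate dehydrogenase, averaged 85.3 ± 14.9 FPKM in vehicle and 94.2 ± 22.8 FPKM in R-2-HG (SD, n = 3), and Idh2 averaged 7.40 ± 0.894 and 7.74 ± 0.917 FPKM. D2hgdh, which oxidises R-2-HG, averaged 1.84 ± 0.363 and 1.80 ± 0.203 FPKM. Hif1a stood at 22.9 ± 2.26 and 24.1 ± 3.98 FPKM, and Ldha, which makes lactate, at 111 ± 14.5 and 106 ± 14.2 FPKM. The 2-oxoglutarate-dependent enzymes Tet2, a DNA demethylase, and Fto, an RNA demethylase, averaged 1.59 ± 0.821 and 3.23 ± 0.304 FPKM in vehicle and 1.45 ± 0.683 and 2.81 ± 0.223 FPKM in R-2-HG.

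No gene passed the test. Of 9701 genes tested with limma, 0 had an adjusted p under 0.05 (smallest adjusted p = 0.99998), and 140 had an unadjusted p under 0.05, 67 with a higher and 73 with a lower mean after R-2-HG, where 485 would be expected by chance among exchangeable libraries. The libraries pair by replicate number, and the other 3 splits of the 6 libraries that part all pairs gave 123, 145 and 146 such genes. With the replicate number as a block the count was also 0, with 329 genes at an unadjusted p under 0.05. For 9173 genes (94.6%) the 95% interval of the change lay within 1 unit of 0 on the log2(FPKM + 1) scale, which for genes of a few FPKM allows a change in FPKM of well over 2-fold, and the same held for 3317 (97.1%) of the 3417 genes with a mean of at least 10 FPKM. On the log2(FPKM + 1) scale the 95% interval ran from -0.35 to 0.60 for Idh1, -0.39 to 0.26 for Ldha, -0.27 to 0.40 for Hif1a, -0.37 to 0.34 for D2hgdh and -0.78 to 0.65 for Tet2. The 3 libraries of one group all lay above those of the other for 455 genes (4.7%), 197 higher and 258 lower with R-2-HG, against 10% by chance among exchangeable libraries and 462, 484 and 523 genes in those 3 other splits.

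Genes read as markers of macrophage activation did not pass either, and Arg1 and Mrc1 varied more within the groups than between them. Arg1, which encodes arginase 1, stood at 192, 64.1 and 8.81 FPKM in vehicle libraries 1, 2 and 3 and 179, 83.3 and 14.4 FPKM in R-2-HG libraries 1, 2 and 3. Mrc1, the mannose receptor, averaged 20.9 ± 6.54 FPKM in vehicle and 20.2 ± 6.40 FPKM in R-2-HG (SD, n = 3). Tnf averaged 2.64 ± 0.177 and 3.39 ± 1.45 FPKM, and its value in R-2-HG library 3, 5.07 FPKM, stood above the other 5 libraries. Il1b averaged 0.863 ± 0.278 and 1.39 ± 1.16 FPKM. The inflammatory or regulatory genes Nos2, Il6 and Il10 lay below the filter and near the detection limit. Nos2 averaged 0.0958 ± 0.140 FPKM in vehicle and 0.00973 ± 0.0168 FPKM in R-2-HG. Il6 was listed at 0 in all 3 vehicle libraries and at 0.090, 0 and 0.033 FPKM in the R-2-HG libraries, and Il10 averaged 0.0161 ± 0.0279 FPKM in vehicle and 0.0714 ± 0.0864 FPKM in R-2-HG.

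**Figure D1:**
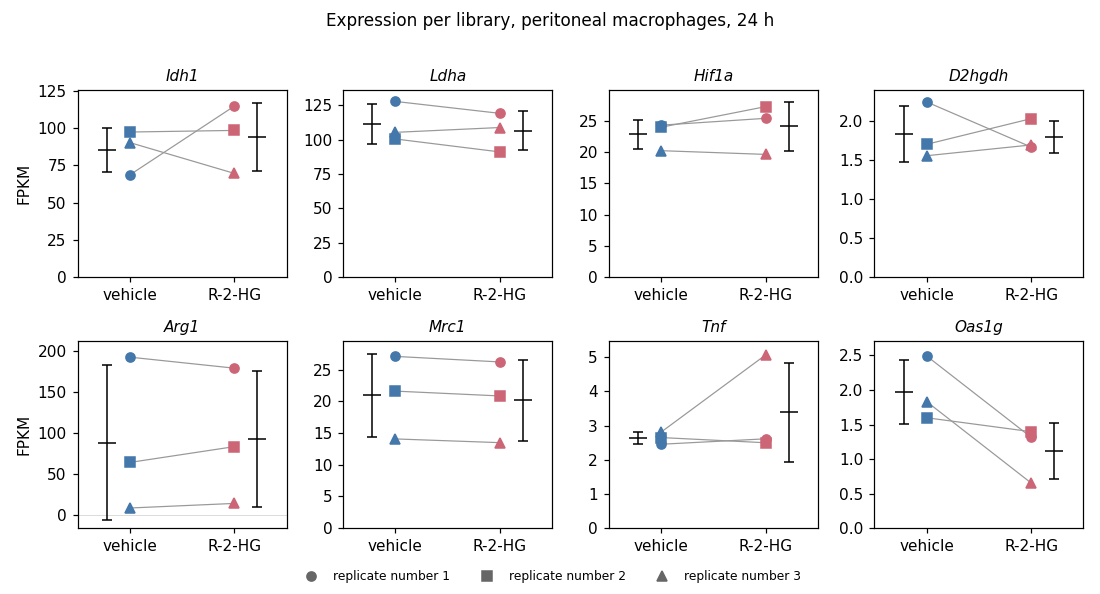
FPKM of 8 genes per library (y axis) in vehicle and R-2-HG (x axis). Marker shapes give the replicate number, grey lines join libraries of the same number, and black bars give the mean ± SD of 3 libraries, with Arg1 between 8.81 and 192 FPKM over the 6 libraries and Mrc1 means of 20.9 and 20.2 FPKM.

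As no gene passed, the 5 genes with the smallest p in each direction are given, all of which missed the threshold (adjusted p = 0.99998, limma). Lower with R-2-HG in every pair of the same replicate number were Ttpal, which encodes a tocopherol transfer protein-like factor (chromosome 2, 163602314 to 163619013, GRCm38), at 2.71 ± 0.459 FPKM in vehicle and 0.797 ± 0.275 FPKM in R-2-HG (SD, n = 3; log2 change -1.05, SE 0.18), and Gatad2b, a subunit of the NuRD chromatin complex (chromosome 3, 90293178 to 90363407), at 5.63 ± 0.241 and 2.08 ± 1.32 FPKM (-1.19, SE 0.27). Fam89b (chromosome 19, 5728087 to 5729653) averaged 7.65 ± 0.758 and 4.03 ± 0.933 FPKM, Gm7879 (chromosome 5, 43913144 to 43913917) 1.63 ± 0.0924 and 0.50 ± 0.202 FPKM, and the pseudogene Gm18953 (chromosome 2, 90239483 to 90241423) 9.90 ± 1.94 and 5.20 ± 0.905 FPKM. Higher with R-2-HG in every pair were Sap18, a subunit of the Sin3 histone deacetylase complex (chromosome 14, 57798180 to 57806638), at 0.851 ± 0.878 FPKM in vehicle and 3.41 ± 0.410 FPKM in R-2-HG (1.34, SE 0.29), Zbtb42 (chromosome 12, 112678828 to 112682747) at 0.506 ± 0.201 and 2.67 ± 1.21 FPKM (1.23, SE 0.27), and Acadsb, an acyl-CoA dehydrogenase (chromosome 7, 131410601 to 131448944), at 3.53 ± 0.838 and 6.20 ± 0.261 FPKM (0.68, SE 0.15). The pseudogenes Gm13340 (chromosome 2, 22588103 to 22589647) and Apoo-ps (chromosome 13, 107414144 to 107414729) averaged 38.4 ± 4.38 and 1.63 ± 0.575 FPKM in vehicle and 59.4 ± 11.7 and 3.22 ± 0.429 FPKM in R-2-HG. Exons of Fam89b overlap Sssca1 on the same strand, those of Sap18 a microRNA on the same strand and Ska3 on the opposite strand, those of Gatad2b a model on the opposite strand, and the pseudogenes can share reads with their parent genes, so these values are uncertain.

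A few genes, chosen after their values were seen, were called when libraries were left out. The cause of these calls was not tested. Without R-2-HG library 1, limma called 1 gene, Ube2l3, a ubiquitin-conjugating enzyme (log2 change 2.83, SE 0.17, adjusted p = 0.00804), which stood at 2.69, 2.0 and 2.79 FPKM in vehicle libraries 1, 2 and 3 and 2.48, 21.4 and 26.4 FPKM in R-2-HG libraries 1, 2 and 3. Exons of Ube2l3 overlap Ydjc on the opposite strand. Without R-2-HG library 3, 1 gene was called, C5ar1, the complement C5a receptor (log2 change -2.14, SE 0.16, adjusted p = 0.0347), which stood at 18.8, 13.6 and 16.4 FPKM in vehicle libraries 1, 2 and 3 and 2.97, 2.77 and 17.9 FPKM in R-2-HG libraries 1, 2 and 3. With the number as a block, Ube2l3 was called without both libraries of number 1 (2.88, adjusted p = 0.0124). Without both libraries of number 3, 4 genes were called: C5ar1 (-2.13, adjusted p = 0.0160), Gatad2b (-1.52, adjusted p = 0.0367), the immunoglobulin gene Igkc (-0.90, adjusted p = 0.0362) and the adaptor gene Grb2 (0.95, adjusted p = 0.0367). In the pair left out, C5ar1, Igkc and Grb2 went the other way, while Gatad2b was lower (5.55 FPKM in vehicle and 3.59 FPKM in R-2-HG). The first stood at 16.4 FPKM in vehicle library 3 and 17.9 FPKM in R-2-HG library 3. Igkc and Grb2 stood at 49.1 and 71.7 FPKM in vehicle library 3 and 55.3 and 68.3 FPKM in R-2-HG library 3. With all libraries the log2 changes of Igkc and Grb2 were -0.54 and 0.61. Over all alternatives the smallest adjusted p of a gene lay between 0.00804 and 1.

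With camera at the preset correlation, the interferon-stimulated genes came nearest to a call among the 29 gene lists. By unadjusted p, the 2-hydroxyglutarate and glutamate metabolism list came before them with an estimated correlation (0.273 against 0.351) and with fry (0.362 against 0.519). Of the 43 interferon-stimulated genes listed, 32 were tested, 24 with a lower and 8 with a higher mean after R-2-HG, and the median log2 change was -0.11 (camera adjusted p = 0.0597 over 29 lists, not passing; adjusted p = 0.982 with an estimated correlation). Oas1g, an oligoadenylate synthetase, averaged 1.97 ± 0.464 FPKM in vehicle and 1.12 ± 0.408 FPKM in R-2-HG (SD, n = 3), Gbp2, a guanylate-binding protein, 10.7 ± 4.43 and 6.39 ± 0.860 FPKM, and Irf9, a part of the transcription factor ISGF3, 4.38 ± 0.353 and 3.53 ± 0.464 FPKM. Over all genes tested and adjusted over the list alone, 0 members passed, with 1 at an unadjusted p under 0.05. Of the members, 8 were lower and 1 was higher with R-2-HG in all 3 pairs of the same replicate number. The list passed without a filter on low values (adjusted p = 0.0128), after quantile normalization (adjusted p = 0.0383), without R-2-HG library 1 (adjusted p = 0.0309), without vehicle library 3 (mean log2 change -0.28, adjusted p = 1.36e-10), and with the replicate number as a block and both libraries of number 3 left out (-0.27, adjusted p = 8.53e-09). With an estimated correlation (0.33 for the interferon-stimulated genes with all libraries) 0 of the 29 lists passed in any of the fits with libraries left out, where the smallest adjusted p was 0.645. So few libraries leave that test little power, so this does not decide whether the calls hold. At the preset correlation, 6 other lists passed with lower means in the block without number 3, among them both RNA quality lists of ribosomal protein (-0.096, adjusted p = 0.000229) and mitochondrially encoded genes (-0.14, adjusted p = 0.0209). The mean change of the interferon-stimulated genes was 0.003 without vehicle library 1 (adjusted p = 0.999, the highest of its alternatives). The mean of their log2 values was 2.97, 2.76 and 2.40 in vehicle libraries 1, 2 and 3 and 2.65, 2.54 and 2.56 in R-2-HG libraries 1, 2 and 3. It was lowest in vehicle library 3 and highest in vehicle library 1, so leaving out either shifts the change in a direction set beforehand. In vehicle library 1, where this mean was highest, some lymphocyte markers were also at their highest, among them Ighm, Cd3e, Cd3d (0.957 FPKM, at most 0.139 in the other 5) and Nkg7 (0.435 FPKM, at most 0.202 in the other 5).

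None of the other 28 lists passed either, and their smallest camera adjusted p was 0.749. Across all 29 lists 0 passed with camera, with an estimated correlation (smallest adjusted p = 0.982) or with fry (smallest adjusted p = 0.98), and no list held a member called over all genes or adjusted over the list alone. In what follows, the median is the median log2 change of a list's tested members, the p is camera's adjusted p over the 29 lists, and changes of single genes are log2 change ± SE on log2(FPKM + 1). Of single members of these 28 lists, 1 had an unadjusted p under 0.05.

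No list of energy metabolism passed with all 6 libraries. Among HIF targets and glycolysis genes, 22 of 30 tested had a lower mean with R-2-HG (median -0.04, adjusted p = 0.749), with P4ha1, a prolyl hydroxylase subunit of collagen synthesis, at -0.20 ± 0.18 and the glycolytic regulator Pfkfb3 at -0.41 ± 0.36. In the tricarboxylic acid cycle list 15 of 22 were lower and 7 higher (median -0.03, adjusted p = 0.749), with 8 lower and 0 higher in all 3 pairs of the same replicate number. There Dld, a dehydrogenase subunit, stood at 0.22 ± 0.11, the succinyl-CoA ligase gene Suclg2 at -0.32 ± 0.17 and Dlst, a part of the 2-oxoglutarate dehydrogenase complex, at -0.17 ± 0.10. Of the nuclear genes of oxidative phosphorylation 32 of 52 were lower (median -0.02, adjusted p = 0.812), among them Ndufb9 at -0.19 ± 0.12, while Atp5l was at 0.40 ± 0.23. This list passed in the block without both libraries of number 3 (mean log2 change -0.06, adjusted p = 0.0209, up to 0.999 over the alternatives), and not there with an estimated correlation (smallest adjusted p of any list 0.749). Fatty acid uptake and oxidation had 16 of 27 members higher (median 0.03, adjusted p = 0.749), with Acadl, the long-chain acyl-CoA dehydrogenase, at -0.12 ± 0.10 and the carnitine carrier Slc25a20 at -0.14 ± 0.13.

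The lists tied to 2-hydroxyglutarate and to sterols did not pass with all 6 libraries. For 2-hydroxyglutarate and glutamate metabolism 13 of 19 members were lower (median -0.06, adjusted p = 0.749), with Glul, glutamine synthetase, at -0.10 ± 0.09 and the alanine transaminase Gpt at -0.26 ± 0.20. For the 2-oxoglutarate-dependent dioxygenases 26 of 40 were lower (median -0.04, adjusted p = 0.749), with the ribosomal protein hydroxylase Ogfod1 at -0.53 ± 0.26 and Jmjd8 at 0.31 ± 0.22. Cholesterol biosynthesis and SREBP targets had 15 of 23 members lower (median -0.03, adjusted p = 0.812). Lanosterol synthase, Lss, stood at -0.24 ± 0.15 and squalene synthase, Fdft1, at 0.24 ± 0.17. In the LXR targets and lipid efflux list 9 of 18 members were higher and 9 lower (median 0.01, mean -0.01, adjusted p = 0.899), with the apolipoprotein gene Apoc1 at -0.68 ± 0.36, Lpcat3 at -0.18 ± 0.13 and the apolipoprotein gene Apoe at 0.42 ± 0.33.

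Inflammatory and activation lists did not pass with all 6 libraries. Of the NF-kB inflammatory genes 14 of 24 had a higher mean (median 0.04, adjusted p = 0.812), with the chemokine gene Ccl3 at 0.18 ± 0.13 and Nfkb1 at -0.17 ± 0.15. This list passed without vehicle library 1 (mean log2 change 0.18, adjusted p = 0.0300, against up to 0.999 under its other alternatives), and not in the same fit with an estimated correlation (smallest adjusted p of any list 0.999). Of the alternative activation genes 9 of 15 were higher (median 0.03, adjusted p = 0.899), with the transcription factor gene Egr2 at -0.27 ± 0.17 and Retnla at 0.15 ± 0.17. The class II antigen presentation list was evenly divided, 6 higher and 6 lower (median -0.003, adjusted p = 0.923), with H2-DMa at -0.30 ± 0.30 and Ciita, the class II transactivator, at -0.28 ± 0.31. Interleukin-10, prostaglandin and immune checkpoint genes had 13 of 21 lower (median -0.04, adjusted p = 0.812), with Tnfaip8l2 at -0.28 ± 0.15 and the receptor gene Il10ra at 0.30 ± 0.20. Of the immediate early genes 12 of 23 were lower (median -0.002, adjusted p = 0.880), with Junb at 0.17 ± 0.11. Of the aryl hydrocarbon receptor and tryptophan genes 5 were tested, 2 higher and 3 lower (median -0.008, adjusted p = 0.940), with Tiparp at 0.13 ± 0.12 and the quinone reductase Nqo1 at -0.33 ± 0.34.

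Lists of macrophage identity and function did not pass with all 6 libraries. The large peritoneal macrophage identity genes had 14 of 21 lower (median -0.03, adjusted p = 0.749), with Icam2 at -0.16 ± 0.14 and Itgam, the CD11b integrin chain, at -0.39 ± 0.30. The Itgam symbol is carried by 2 gene models that can split reads. The more abundant one, whose change is given, averaged 99.99 ± 4.92 FPKM in vehicle and 81.8 ± 34.6 FPKM in R-2-HG. The other averaged 34.0 ± 31.4 and 61.4 ± 73.7 FPKM. Their sum averaged 134 ± 35.8 and 143 ± 50.4 FPKM, so the direction turns when both are counted. The small peritoneal macrophage and monocyte genes had 7 of 15 higher (median -0.03, mean 0.005, adjusted p = 0.839), with Fcrls at 0.33 ± 0.21. Among phagocytosis and scavenger receptors 21 of 34 were lower (median -0.02, adjusted p = 0.969), with Fcgr4, a receptor for IgG, at -0.22 ± 0.28. Lysosome and autophagy genes, which include some of the most abundant transcripts here, had 22 of 43 lower (median -0.009, adjusted p = 0.839), with the proton pump subunit gene Atp6v0d1 at -0.14 ± 0.12 and the transcription factor gene Tfec at -0.23 ± 0.23. Extracellular matrix and remodelling genes had 16 of 28 lower (median -0.05, adjusted p = 0.839), with the metalloproteinase genes Mmp9 at -0.27 ± 0.27 and Mmp8 at -0.25 ± 0.27. Without vehicle library 3 the extracellular matrix list passed (mean log2 change -0.46, adjusted p = 0.00319), as did class II antigen presentation (-0.36, adjusted p = 0.000602), cholesterol biosynthesis (-0.13, adjusted p = 0.00215), phagocytosis (-0.16, adjusted p = 0.0184) and large macrophage identity (-0.17, adjusted p = 0.0323). None of them passed in that fit with an estimated correlation (smallest adjusted p of any list 0.645). Without R-2-HG library 1 the extracellular matrix list passed too (-0.47, adjusted p = 0.0104), and without vehicle library 1 it passed in the other direction (0.27, adjusted p = 0.0369). Neither fit called the list with an estimated correlation (smallest adjusted p of any list 0.890 and 0.999), a test of little power with so few libraries. Leaving out 1 library leaves its partner of the same number, so these fits mix treatment with replicate number. With the number as a block and both libraries of number 3 left out, class II (-0.14, adjusted p = 0.0209) and extracellular matrix genes (-0.15, adjusted p = 0.0293) passed with smaller changes, but not with an estimated correlation (smallest adjusted p of any list 0.749). Cholesterol biosynthesis, phagocytosis and large macrophage identity did not pass there. The highest adjusted p over the alternatives was 0.999 for each of these lists.

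Stress, growth and quality lists complete the comparison. NRF2 antioxidant genes had 22 of 26 lower (median -0.05, adjusted p = 0.749), with the ferritin light chain gene Ftl1 at -0.21 ± 0.13 and Gclm, a subunit of the first enzyme of glutathione synthesis, at 0.29 ± 0.21. They passed in the block without both libraries of number 3 (mean log2 change -0.08, adjusted p = 0.0273, up to 0.999 over the alternatives), and not there with an estimated correlation (smallest adjusted p of any list 0.749). Iron handling, which also holds Ftl1, had 9 of 14 lower (median -0.01, adjusted p = 0.839), with Slc25a37, the mitochondrial iron importer, at 0.17 ± 0.12. ATF4 and unfolded protein response genes had 18 of 34 higher (median 0.02, adjusted p = 0.880), with Trib3 at 0.39 ± 0.22 and Dnajb9 at -0.16 ± 0.12. The p53 targets and apoptosis list had 16 of 25 higher (median 0.04, adjusted p = 0.812), with the death receptor gene Fas at -0.28 ± 0.16 and Aen at 0.28 ± 0.19. Cell cycle genes had 9 of 17 lower (median -0.03, adjusted p = 0.812), with the checkpoint kinase gene Bub1b at -0.62 ± 0.29 and the helicase subunit gene Mcm2 at -0.29 ± 0.22. Replication-dependent histones had 3 of 6 higher (median -0.005, mean 0.10 and camera direction down, adjusted p = 0.969), with Hist3h2a at -0.13 ± 0.12 and Hist1h4i at 0.54 ± 0.62.

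As to RNA quality, cytosolic ribosomal protein genes had 43 of 65 lower (median -0.04, adjusted p = 0.749), with Rps12 at -0.25 ± 0.12 and Rps6 at 0.36 ± 0.18, values that reads shared with processed pseudogenes leave uncertain. They passed without R-2-HG library 3 (mean log2 change -0.09, adjusted p = 0.000775) and in the other direction without R-2-HG library 2 (0.05, adjusted p = 0.0315, up to 0.999 over the alternatives). With an estimated correlation neither fit called them (smallest adjusted p of any list 0.842 and 0.989). Mitochondrially encoded genes had 10 of 13 higher (median 0.04, mean -0.01, adjusted p = 0.839), with mt-Nd5 at 0.15 ± 0.15 and mt-Nd6, the member with an unadjusted p under 0.05, at -0.65 ± 0.28. This list passed without R-2-HG library 2 (mean log2 change 0.10, adjusted p = 0.0252). It passed in the other direction in the block without both libraries of number 3 (-0.14, adjusted p = 0.0209). It passed in neither fit with an estimated correlation (smallest adjusted p of any list 0.989 and 0.749). Heat shock and dissociation genes had 6 of 11 lower (median -0.02, adjusted p = 0.812), with Hspa1a at -0.21 ± 0.17 and Hspd1 at -0.15 ± 0.12. The sign of the mean differed from that of the median in 4 lists (small peritoneal macrophage, replication-dependent histone, mitochondrially encoded and LXR target genes) and from the direction of camera in 4 (LXR target, aryl hydrocarbon receptor, mitochondrially encoded and histone genes).

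**Figure D2:**
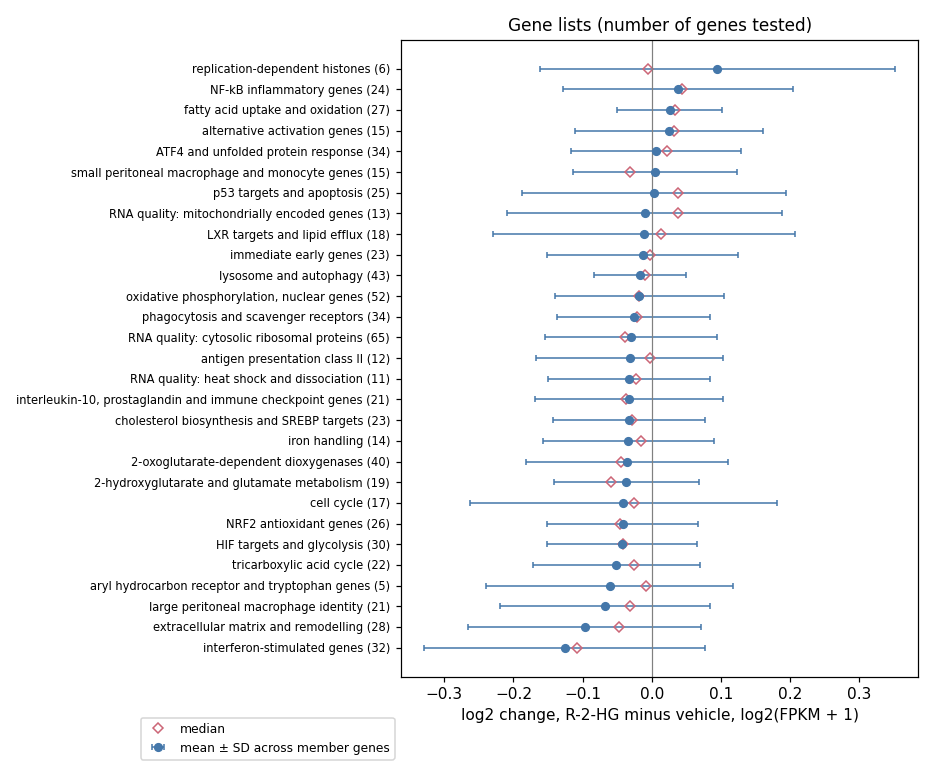
Log2 change, R-2-HG minus vehicle (x axis), of the 29 gene lists (y axis, with the number of genes tested). Filled points and bars give the mean ± SD across member genes and open diamonds the median, which lay between -0.11 and 0.04 for all 29 lists.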

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

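Tests without both libraries of a replicate number, with array weights and with an estimated correlation in the block or with libraries left out, and the other filters and median centring for lists, were chosen after the results were seen. The count of genes called was 0 under every alternative with all 6 libraries: a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, quantile normalization, median centring, eBayes without robust estimation, a 2-fold minimum, array weights and the replicate block, which changed no call of a gene or list. Genes at an unadjusted p under 0.05 numbered 140 in the fit without the block, between 52 (filter at 5 FPKM) and 303 (no filter, 17294 genes tested) under the alternatives with all 6 libraries and no block, and 329 with the block. Leaving out a library, or both libraries of a replicate number in the block, gave 0 to 4 genes. Both libraries of number 3 left out gave 4 (Gatad2b, Igkc, C5ar1 and Grb2), and Ube2l3 was called both without R-2-HG library 1 and without both libraries of number 1. The smallest adjusted p over the alternatives lay between 0.00804 and 1. Fewer samples enter these fits, and the cause of the calls was not tested.

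The count of lists called was 1 without a filter on low values and 1 after quantile normalization, the interferon-stimulated genes (mean log2 change -0.14 and -0.12), and 0 under the other alternatives with all 6 libraries, the replicate block included. With the preset correlation it was 0 to 7 with libraries left out, highest without both libraries of number 3, where the interferon-stimulated, class II, nuclear oxidative phosphorylation, NRF2, extracellular matrix, ribosomal protein and mitochondrially encoded lists passed with lower means. With an estimated correlation it was 0 in each of those fits (smallest adjusted p 0.645), where so few libraries leave that test little power. With libraries left out, the mean change of the interferon-stimulated genes ran from -0.28 (without vehicle library 3) to 0.003 (without vehicle library 1), and the adjusted p over all its alternatives from 1.36e-10 to 0.999. The cause was not tested. The alternative planned for counts only was not run.

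Of 1377 values of named genes under alternatives, 1334 kept their direction and side of the threshold and 36 reversed, while 7 passed in the same direction. Of 811 list values, 635 kept both, 157 reversed and 19 passed in the same direction. Each fit with libraries left out enters the list values with the preset and again with an estimated correlation. The mean change is the same in both, so a reversal there is counted under each. Of the reversed values 3 passed, each with a library left out: extracellular matrix (0.27, adjusted p = 0.0369), without vehicle library 1, and ribosomal proteins (0.050, 0.0315) and mitochondrially encoded genes (0.099, 0.0252), both without R-2-HG library 2. With an estimated correlation none passed in the same fits (smallest adjusted p of any list 0.999 and 0.989). The adjusted p over the alternatives ran up to 0.999 for each. The cause was not tested. As mean log2 changes, reversals with all 6 libraries were p53 targets and apoptosis at -0.002 with a pseudocount of 0.1, alternative activation genes at -0.034, small peritoneal macrophage and monocyte genes at -0.039 and replication-dependent histones at -0.004 without a filter, and NF-kB inflammatory genes at -0.006, LXR targets and lipid efflux at 0.035, ATF4 and unfolded protein response at -0.018, cell cycle at 0.044, p53 targets and apoptosis at -0.008 and small peritoneal macrophage and monocyte genes at -0.009 with the filter at 5 FPKM. With array weights they were Ldha at 0.009, Mrc1 at 0.064, antigen presentation class II at 0.021, oxidative phosphorylation (nuclear genes) at 0.009, LXR targets and lipid efflux at 0.021, cell cycle at 0.007, phagocytosis and scavenger receptors at 0.022, extracellular matrix and remodelling at 0.13, interleukin-10, prostaglandin and immune checkpoint genes at 0.035, aryl hydrocarbon receptor and tryptophan genes at 0.061 and replication-dependent histones at -0.013.

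With libraries left out, the lowest and highest mean log2 changes of the lists besides the interferon-stimulated genes were as follows, first for the lists that reversed. They were -0.081 to 0.008 for HIF targets and glycolysis, -0.094 to 0.18 for NF-kB inflammatory genes, -0.13 to 0.18 for alternative activation genes, -0.36 to 0.19 for antigen presentation class II, -0.062 to 0.043 for oxidative phosphorylation (nuclear genes) and -0.13 to 0.033 for cholesterol biosynthesis and SREBP targets. The range was -0.063 to 0.037 for LXR targets and lipid efflux, -0.024 to 0.073 for fatty acid uptake and oxidation, -0.088 to 0.017 for NRF2 antioxidant genes, -0.023 to 0.040 for ATF4 and unfolded protein response, -0.15 to 0.032 for cell cycle and -0.032 to 0.039 for p53 targets and apoptosis. Ranges were -0.044 to 0.019 for lysosome and autophagy, -0.16 to 0.12 for phagocytosis and scavenger receptors, -0.18 to 0.041 for large peritoneal macrophage identity, -0.19 to 0.17 for small peritoneal macrophage and monocyte genes, -0.039 to 0.023 for immediate early genes and -0.47 to 0.27 for extracellular matrix and remodelling. Further ranges were -0.12 to 0.077 for interleukin-10, prostaglandin and immune checkpoint genes, -0.25 to 0.12 for aryl hydrocarbon receptor and tryptophan genes, -0.10 to 0.025 for iron handling, -0.096 to 0.050 for cytosolic ribosomal proteins, -0.14 to 0.10 for mitochondrially encoded genes and -0.51 to 0.52 for replication-dependent histones. Lists that did not reverse were the tricarboxylic acid cycle (-0.096 to -0.006), 2-hydroxyglutarate and glutamate metabolism (-0.078 to -0.010), 2-oxoglutarate-dependent dioxygenases (-0.089 to -0.001) and heat shock and dissociation (-0.063 to -0.006).

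For the single named genes that reversed with libraries left out, the lowest and highest log2 changes were -0.10 to 0.12 for D2hgdh, -0.18 to 0.37 for Idh1, -0.018 to 0.14 for Idh2, -0.36 to 0.17 for Tet2, -0.026 to 0.20 for Hif1a and -0.15 to 0.042 for Ldha. They were -0.86 to 1.31 for Arg1, -0.30 to 0.20 for Mrc1, -0.032 to 0.37 for Tnf, -0.18 to 0.72 for Il1b, -0.055 to 0.32 for Retnla and -0.018 to 0.49 for Gclm. Ranges were -0.37 to 0.006 for Tfec, -0.66 to 0.013 for Itgam, -0.45 to 0.016 for Fcgr4, -0.47 to 0.022 for Mmp8, -0.005 to 0.52 for Il10ra and -0.047 to 0.29 for mt-Nd5. The range was -0.30 to 1.46 for Hist1h4i. Other named genes kept their direction, some with changes that also moved far, such as Atp5l (0.023 to 0.639), Ogfod1 (-0.745 to -0.116), Gpt (-0.462 to -0.052) and Slc25a20 (-0.227 to -0.014).

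Depth of 13680000 to 16610000 fragments limits low genes: with 1 fragment of a 2 kb transcript worth 0.0301 to 0.0365 FPKM, Nos2, Il6 and Il10 rest on few fragments, and small changes in them were not detectable at this depth. They lay below the filter and were not tested. Their highest values in an R-2-HG library were 0.029, 0.09 and 0.167 FPKM, in the order named.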

Other observations

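The tests reported here were chosen after the results were seen, except the comparison of the groups with all libraries, the fit with the replicate number as a block and the fits without 1 library. Libraries differed by replicate number far more than by treatment. With the number as a term of the limma model, 155 of 9701 genes differed between numbers (adjusted p under 0.05, 2034 at an unadjusted p under 0.05), against 0 (329 unadjusted) between R-2-HG and vehicle in the same fit, and the genes named here were chosen after their values were seen. Of the 155, 104 had their highest mean in number 1 and 109 their lowest in number 3. The smallest adjusted p, 0.00522, was that of Arg1. Values that follow are in the same order, numbers 1, 2 and 3. The class II genes H2-Aa and Cd74, which present peptides to T cells, stood at 223, 157 and 50.7 FPKM in vehicle libraries 1, 2 and 3 and 197, 143 and 59.3 FPKM in R-2-HG libraries 1, 2 and 3 and at 699, 444 and 143 FPKM in vehicle libraries 1, 2 and 3 and 616, 418 and 180 FPKM in R-2-HG libraries 1, 2 and 3. The complement gene C3 stood at 48.4, 19.9 and 6.16 FPKM in vehicle libraries 1, 2 and 3 and 42.5, 20.1 and 6.23 FPKM in R-2-HG libraries 1, 2 and 3, the scavenger receptor gene Marco at 100, 36.2 and 27.8 FPKM in vehicle libraries 1, 2 and 3 and 91.4, 35.4 and 30.8 FPKM in R-2-HG libraries 1, 2 and 3 and the collagen gene Col3a1 at 19.5, 2.31 and 0.471 FPKM in vehicle libraries 1, 2 and 3 and 12.7, 1.14 and 0.248 FPKM in R-2-HG libraries 1, 2 and 3. The linker histone gene Hist1h1c was highest in number 3, at 56.4, 62.2 and 133 FPKM in vehicle libraries 1, 2 and 3 and 55.7, 59.3 and 137 FPKM in R-2-HG libraries 1, 2 and 3.

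Of the fixed lists, 5 held more of the 155 genes than chance gives (Fisher's exact test, adjusted over 29 lists). These were extracellular matrix and remodelling with 15 of 28 genes (adjusted p = 5.16e-19), phagocytosis and scavenger receptors with 10 of 34 (1.11e-09), small peritoneal macrophage and monocyte genes with 6 of 15 (6.49e-07), class II antigen presentation with 4 of 12 (0.000204) and alternative activation with 4 of 15 (0.000433). Genes within a list are not independent, so these p-values are too small. The interferon-stimulated genes held 0 of 32. The count of 155 ran from 116 (pseudocount 0.1) to 174 (filter at a mean of 5 FPKM) under 5 of 6 alternatives and was 0 without a filter (17294 genes, smallest adjusted p = 0.0914, 2631 genes at an unadjusted p under 0.05), so it rests on the filter.

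Sequencing depth is argued against as the source of the differences between replicate numbers, since the mean depths of the numbers differed by at most 1.102 times. A differing share of fibroblasts and mesothelial cells could raise collagen genes, but not alone class II genes, whose median log2 ratio of number 1 to number 3 was 0.711 (SD 0.675 over 12 genes, all 12 higher in number 1). Of the 6 ways to pair vehicle with R-2-HG libraries, the pairing by number gave 155 genes and the highest other 1; only 1 pairing, the real one, gave as many, and 6 are too few for a share under 0.05. Both libraries of number 3 had the fewest genes above 0, 13872 (vehicle) and 12817 (R-2-HG), against 14604 to 15270 in the others. Whether this bears on the genes lowest in number 3 was not tested. A differing mix of macrophage states, animals or days stays open and was not tested.

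Of 32 interferon-stimulated genes tested, 24 had a lower and 8 a higher mean with R-2-HG, 8 were lower and 1 was higher in all 3 pairs, and the list did not pass (adjusted p = 0.0597, 0.982 with an estimated correlation, 1.36e-10 to 0.999 over all alternatives). The mean of their log2 values was lower with R-2-HG in pairs 1 and 2 (2.65 against 2.97 and 2.54 against 2.76) and higher in pair 3 (2.56 against 2.40), and the mean log2 change was -0.13 with all libraries, 0.003 without vehicle library 1, -0.28 without vehicle library 3 and -0.27 in the block without both libraries of number 3. Vehicle library 3 had the lowest mean of the list and pair 3 alone rose, so leaving out that library or pair must enlarge the fall. Vehicle library 1 had the highest mean of the list, so leaving it out must shrink the change, which does not show whether that library is the source. Of the lymphocyte markers, Ighm (32.4 FPKM, 4.56 to 8.03 in the other 5), Cd3d (0.957, 0 to 0.139), Cd3e (0.705, 0 to 0.256), Nkg7 (0.435, 0 to 0.202), Trac (0.79, 0 to 0.587) and Cd8a (0.066, 0 to 0.032) were highest in that library too, as was the immunoglobulin gene Igkc (94.6, 30.8 to 56.5), while Cd79a, Cd79b, Ms4a1, Pax5 and Klrb1c were not. Of the 10 splits of the 6 libraries into 3 and 3, 6, the real one included, gave a mean change as large in either direction, the real one at 0.126 and the highest other at 0.290. Splits that keep libraries of a number together also carry the differences between numbers. Among the splits that part all 3 pairs, the real one gave 0.126 and the others 0.231, 0.018 and 0.088. The 10 splits are too few for a share under 0.05. An effect of R-2-HG, the levels of single libraries and RNA from other cells, which was not tested, stay open.

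R-2-HG library 3 had values above 0 for 12817 genes, the fewest of the 6. Depth is argued against, since it was estimated at 14640000 fragments there and at 13680000 in R-2-HG library 2, which had 14604 genes. Vehicle library 3 had the next fewest genes above 0, 13872. R-2-HG library 3 held 42 single-transcript genes at 2 to 4 fragments, vehicle library 3 held 185 and the others 286 to 379. Fewer distinct transcripts sampled may account for the low counts of R-2-HG library 3: the spread of log2 differences within pair 3 was 1.565 times that of the other pairs at a mean of 1 to 5 FPKM, but also 1.467 times at 100 FPKM and over, so the test does not separate it from a wider spread of all genes. No biological explanation was tested.

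The real split called 0 genes and 0 lists, so each of the 10 splits reaches those counts by construction. The highest other counts were 1 gene and 15 lists, and 10 splits are too few for a share under 0.05. Splits that keep libraries of a number together called up to 15 lists and had up to 1114 genes at an unadjusted p under 0.05, which points to the structure by replicate number. Among the splits that part all 3 pairs, the real one had 140 such genes and 0 lists, and the others had 123, 145 and 146 genes and 2, 1 and 4 lists.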
